A study of Zea mays with 48 samples.

How the data were processed

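RNA from the second leaves of greenhouse seedlings was sequenced from 48 libraries in 16 groups of 3. Each group is one of 4 genotypes at one of 4 times: before inoculation with Exserohilum turcicum (0 h), and 9 h, 3 d and 10 d after it. The genotypes are the parents w22 and B37 and the near-isogenic line of each that carries Htn1. Per the labels' protocols, RNA was isolated with the SV Total RNA kit and libraries were made with the TruSeq Stranded mRNA kit. The labels call leaves at 0 h uninfected and list no mock-inoculated leaves. Leaf age and infection therefore change together between 0 h and every later time. Time of day may change with them, since the labels give no hour of sampling.

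Reads were aligned with STAR to B73 RefGen_v3, per the submitters' processing notes, which give no STAR version. The deposited values are raw read counts per gene, made by the authors with featureCounts 1.4.6 and the AGPv3.29 annotation, per the file headers. The headers of 0 files record a strand option, so the counts are read here as unstranded, and reads from overlapping or antisense genes cannot be told apart. By that tool's default, reads with several alignments are left out, so genes with near-identical copies may be counted low. All lines were aligned to the same B73 genome, so counts may differ between lines through sequence as well as expression, which was not tested. Each library has its own file and replicates were not pooled.

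The files list 39625 genes. Genes of the nucleus were kept, and 123 mitochondrial and 51 chloroplast genes were left out of the tests. Totals ran from 6.5 M to 24.05 M counts per library (M, mega), with a median of 14.86 M. A floor of 3 counts corresponds to 0.125 CPM (counts scaled to the library total, with TMM factors for gene levels) in the deepest library and 0.462 CPM in the shallowest. It covers counting error only. Between replicates, counts varied by more than counting error, with a chi-square per degree of freedom of 4.52 to 106 over 48 pairs of replicates. The lowest Spearman correlation between replicates was 0.961. The common biological coefficient of variation was 19%.

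Symbols came from a table of Zm-B73-REFERENCE-NAM-5.0 genes, used for names only, which lists symbols and synonyms but no products. It matched 19060 of the IDs, 521 of them to several genes, and 2664 IDs got a readable symbol. Where a symbol stands on several IDs, the text adds the ID. Coordinates are those of the deposited annotation on B73 RefGen_v3. What most symbols stand for is not given in the sources used here, and clauses on a gene's known role are general background.

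Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 23353 tested genes, and libraries were scaled with TMM. A model with a mean for each of the 16 groups (32 residual degrees of freedom, trended dispersion, robust fit) was tested with the quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 for that comparison. Every adjusted p of a single gene in the report comes from this test. Log2 fold changes are given with the standard error from the fit. CPM values are means with the SD over 3 libraries, unless another number is given.

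These comparisons were made: each later time against 0 h as the mean of the 4 genotypes; each Htn1 line against its parent at each time; the difference between line and parent in their change from 0 h (the response difference); and the difference between backgrounds in the mean effect of the line. The groups, comparisons, gene lists, rule for naming genes and most alternatives were chosen before the data were examined. Genes called the same way at all 4 times were counted in windows of 5 Mb with at least 5 tested genes, on 10 chromosomes. Each window was tested against all other tested genes with a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. All comparisons among times use the same 0 h libraries, so overlaps between times are not given.

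Named genes have a readable symbol and follow this rule. For each time, they are the 5 highest and 5 lowest log2 fold changes among called genes that moved the same way in all 4 genotypes, with at least 5 CPM in the higher group. For the lines, they are up to 10 higher and 10 lower genes called the same way in both backgrounds at the most times, with at least 2 CPM. For the response differences, they are the 5 highest and 5 lowest per background at the time with the most calls, with at least 5 CPM. Members of the gene lists and wall-associated kinase genes on chromosome 8 may also be named.

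Of 24 gene lists built from symbols, lists for salicylate and for NLR receptors found no member. The others were benzoxazinoid biosynthesis, pathogenesis-related proteins, chitinases and beta-glucanases, phenylpropanoid and lignin, jasmonate and lipoxygenase, ethylene synthesis, WRKY factors, wall-associated kinases, terpenoid phytoalexins, class III peroxidases, glutathione transferases, flavonoid and anthocyanin, proteinase inhibitors, photosystem and light harvesting, mesophyll C4 genes, bundle sheath C4 and Calvin cycle genes, epidermal wax and cutin, dividing cells, senescence and chlorophyll breakdown, heat shock proteins, circadian clock, and cytosolic ribosomal proteins. Lists with at least 3 tested members were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Its p-values were adjusted over the lists of one comparison. Member counts are given over all tested genes and adjusted over the list alone. Some lists took in members by symbol that other names show to have another role, and some of these are named where they moved. The symbol tps also stands for trehalose-phosphate synthases, which the reference does not tell from terpene synthases, so counts of the terpenoid list are not given.

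The test for single genes was tested on simulated counts for w22Htn1 against w22 at 3 d over 22126 genes. It recovered 61 of 100 genes changed by 2-fold and 95 of 100 changed by 4-fold, and called 13 unchanged genes. A comparison with no planted change gave 0 calls. The window test over 23248 genes recovered 200 of 200 planted windows in 20 runs with 0 false calls. The list test recovered 40 of 40 planted lists over 23353 genes with 0 false calls. The simulated values for lists held no correlation between genes, so this result does not cover lists whose genes vary together.

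The alternatives tried were: leaving out each of the 48 libraries in turn; RLE scaling; no filter on low counts; a fit of the compared groups alone; the replicate number as a block; DESeq2 1.42.0; windows of 2 and 10 Mb; camera with an estimated correlation; and fry. A mean over time without the line w22Htn1, and list tests without members of another role, were added after the data had been seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Sequence variants, alternative splicing and fungal reads were not analysed here, since the deposited files hold counts of maize genes only.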

Results

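Gene expression was measured in seedling leaves of 2 maize backgrounds, w22 and B37, each as the recurrent parent and as a near-isogenic line with Htn1. Htn1 confers resistance to Exserohilum turcicum, the fungus of northern corn leaf blight, and was cloned as a wall-associated kinase gene on chromosome 8. The 4 genotypes are called w22, w22Htn1, B37 and B37Htn1. Leaves were taken before inoculation (0 h) and at 9 h, 3 d and 10 d, which the labels match to penetration, biotrophic and necrotrophic growth. Each of the 16 groups had 3 libraries, 48 in all, with totals from 6.5 M to 24.05 M counts (M, mega). The first principal component held 35.6% of the variance and parted the backgrounds, and the second held 16% and parted the libraries at 9 h from the others.

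**Figure D1:**
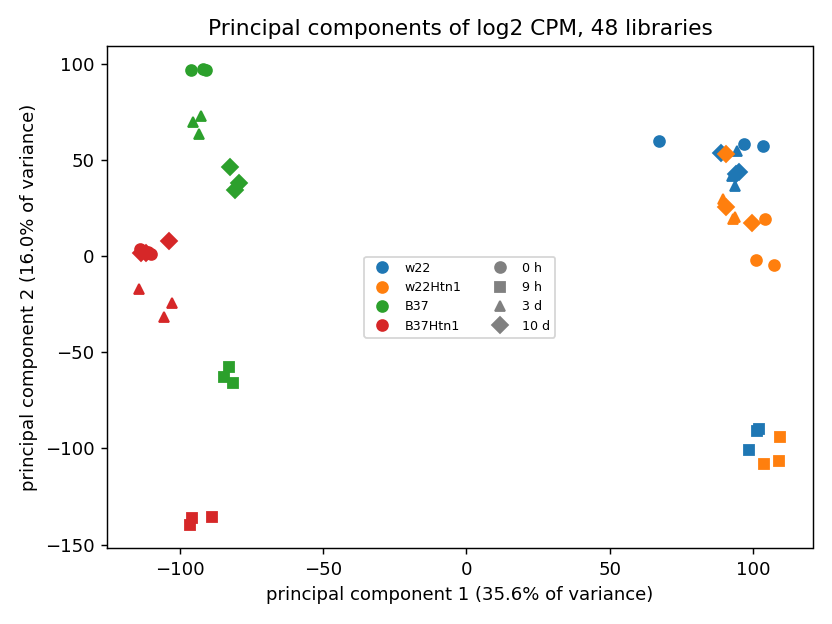
The 48 libraries on the first 2 principal components of log2 CPM, which hold 35.6% and 16% of the variance; colours and symbols give genotype and time. The backgrounds separate along the first component and the libraries at 9 h along the second.

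The comparison with 0 h asks which genes changed during infection. Leaf age changed as well, and time of day may have, since the hour of sampling is not given. Infection, leaf age and time of day cannot be told apart in these changes, including those of clock and photosynthesis genes at 9 h. At 9 h, most genes on the lists of C4 photosynthesis and light harvesting were lower, most of these in all 4 genotypes, and the genes of the circadian clock list were higher. Among single genes, thi1 and thi2 rose strongly, and lpa1, mips2 and nip2b fell. Most ribosomal protein genes were higher on average, but fewer of them in every genotype.

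The gene pep1 (GRMZM2G083841), for the carboxylase that first fixes carbon in C4 leaves, fell by 3.93 ± 0.18 on the log2 scale at 9 h (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.07e-21). In w22 this was a drop from 13447 ± 2621 to 732 ± 287 CPM. The malic enzyme gene me3 fell by 1.63 ± 0.08 and the rubisco activase gene rca3 by 2.32 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 1.35e-19 and 1.09e-12). The light-harvesting gene lhcb6 fell by 3.69 ± 0.35 (edgeR, Benjamini-Hochberg adjusted p = 2e-11). Among clock genes, gigz1a, a homologue of GIGANTEA, rose by 1.76 ± 0.07 and gigz1b by 1.37 ± 0.07 (edgeR, Benjamini-Hochberg adjusted p = 1.58e-23 and 2.09e-19). All of these moved the same way in 4 of 4 genotypes.

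The largest rises under the naming rule were thi2, from 1.25 to 302 CPM (12 libraries each), hao1, from 0.184 to 23.2 CPM, and thi1, from 16.8 to 582 CPM (edgeR, Benjamini-Hochberg adjusted p = 5.98e-23, 3.39e-22 and 4.72e-17). The log2 fold changes of thi2 and thi1 were 7.66 ± 0.28 and 5.25 ± 0.31; hao1 lay near the floor at 0 h. The largest falls included lpa1, named for low phytic acid, from 1122 to 3.59 CPM, and the aquaporin-family gene nip2b, from 196 to 0.903 CPM. The inositol phosphate synthase gene mips2 went from 633 to 6.08 CPM and abc1 from 1841 to 24.3 CPM (edgeR, Benjamini-Hochberg adjusted p = 1.33e-25, 1.2e-29, 9.1e-29 and 6.02e-31 for these 4 falls). The lipoxygenase gene lox12 rose by 4.00 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 7.71e-20). Each of these moved the same way in 4 of 4 genotypes.

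At 9 h 15370 of 23353 tested genes were called, 7918 higher and 7452 lower, of which 3300 and 2477 changed by at least 2-fold. All 4 bundle sheath genes and 5 of 7 mesophyll genes were called lower (4 and 6 adjusted over the list alone), and 8 of 10 photosystem genes were lower and 1 higher, the same counts adjusted over the list alone. All 4 clock genes were higher by both counts. Of 27 ribosomal protein genes, 20 were higher and 4 lower by both counts. Of the called members, 4 of 4 bundle sheath, 5 of 5 mesophyll, 7 of 9 photosystem, 4 of 4 clock and 14 of 24 ribosomal genes, 11 of these higher, moved the same way in all 4 genotypes. Camera called these 5 lists, each at adjusted p = 0.0256; with an estimated correlation the adjusted p was 0.561 for clock, bundle sheath and mesophyll genes and 0.867 for the others. Some members have another role by their names: psat1 is the photosystem member that rose, pdlk1 is a kinase among the mesophyll genes that fell, and GRMZM2G140582 is a clock member known only from a probe name. Genes of dividing cells were called higher in 7 of 10 cases and genes of senescence and chlorophyll breakdown in 3 of 5 with 1 lower, the same counts adjusted over the list alone; camera called neither list (adjusted p = 0.309 and 0.357, and 0.867 for both with an estimated correlation).

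At 3 d the pathogenesis-related gene prp4 was higher than at 0 h in all 4 genotypes. The light-harvesting genes lhcb3 and lhcb7, which had been low at 9 h, were above their level at 0 h. The genes tps10 and igl, for a volatile terpene and for free indole, which wounded maize leaves give off, were lower. The gene prp4 rose by 2.67 ± 0.50, lhcb3 by 1.54 ± 0.35 and lhcb7 by 1.24 ± 0.26 (edgeR, Benjamini-Hochberg adjusted p = 4.05e-05, 0.000503 and 0.000155), each in 4 of 4 genotypes.

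Under the naming rule, sip1, named as stress-induced, rose by 3.45 ± 0.38 and ksl4, of the kaurene synthase family, by 2.90 ± 0.48 (edgeR, Benjamini-Hochberg adjusted p = 4.45e-09 and 8.4e-06). The gene sog1226c rose by 3.12 ± 0.21 and lol3 by 4.00 ± 0.41 (edgeR, Benjamini-Hochberg adjusted p = 1.14e-13 and 7.79e-10). Of the falls, igl, for the enzyme that releases free indole, went from 31.5 to 5.67 CPM (edgeR, Benjamini-Hochberg adjusted p = 1.48e-07). With 1 library left out at a time its log2 fold change lay between −5.00 (without w22 3 d replicate 1) and −3.84. The terpene synthase gene tps10 averaged 40.7 CPM at 0 h and 0.379 CPM at 3 d (edgeR, Benjamini-Hochberg adjusted p = 3.04e-05). Its log2 fold change of −7.71 became −5.61 without B37Htn1 0 h replicate 3, which held 439 CPM, and −8.42 without w22 3 d replicate 1.

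At 3 d 11148 genes were called, 5855 higher and 5293 lower, of which 1535 and 666 changed by at least 2-fold. Camera called 0 of the lists. Pathogenesis-related genes were called higher in 4 of 5 cases, class III peroxidases in 2 of 3 and photosystem genes in 8 of 10, with none lower; adjusted over the list alone, the counts were 4, 2 and 8, with 1 photosystem gene lower. Their camera adjusted p was 0.203, 0.144 and 0.207, and with an estimated correlation 0.898, 0.751 and 0.943. Of the called members, 1 of 4 pathogenesis-related genes, 2 of 2 peroxidases and 5 of 8 photosystem genes moved the same way in all 4 genotypes.

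At 10 d most genes of the anthocyanin pathway and many glutathione transferases were higher on average over the genotypes, but fewer of them in every genotype. The anthocyanin regulator r1 was among the largest rises. Several WRKY factors, regulators of defence genes, rose in all 4 genotypes. The gene tcp30 and the beta-glucosidase gene glu2 fell.

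The transcript of r1 went from 0.0486 CPM, under the floor, to 6.61 CPM (edgeR, Benjamini-Hochberg adjusted p = 4.89e-08), with 14.3 ± 7.53 CPM in B37 and 0.182 ± 0.167 CPM in B37Htn1 at 10 d. Of the pathway genes, chi1 (chalcone isomerase) rose by 2.33 ± 0.31, c2 by 0.88 ± 0.16 and bz2 by 1.62 ± 0.26, each in 4 of 4 genotypes (edgeR, Benjamini-Hochberg adjusted p = 1.35e-07, 2.67e-05 and 2.1e-06). The flavanone hydroxylase gene fht1, at 0 CPM in B37 at 0 h and at 52.5 CPM at 10 d, rose in 3 of 4 genotypes (edgeR, Benjamini-Hochberg adjusted p = 1.48e-06). The factors wrky104 and wrky42 rose by 3.65 ± 0.50 and 2.22 ± 0.30, in 4 of 4 genotypes (edgeR, Benjamini-Hochberg adjusted p = 1.83e-07 and 9.64e-08). At 0 h wrky104 lay under the floor in B37 and w22Htn1, at 0.0557 and 0.0719 CPM. It was at 0.531 CPM in w22 and 1.89 CPM in B37Htn1. The largest falls included tcp30, by 3.30 ± 0.22, and glu2, by 4.95 ± 0.67 (edgeR, Benjamini-Hochberg adjusted p = 8.64e-14 and 2.06e-07); the value for glu2 was −5.69 without B37 10 d replicate 3. The chlorophyll breakdown gene sgr2 rose by 1.11 ± 0.22 in 4 of 4 genotypes (edgeR, Benjamini-Hochberg adjusted p = 5.92e-05).

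At 10 d 12474 genes were called, 6425 higher and 6049 lower, of which 2377 and 541 changed by at least 2-fold. Of 8 flavonoid genes 7 were higher and 0 lower, and of 29 glutathione transferases 16 were higher and 1 lower, the same counts adjusted over the list alone. Camera called both (adjusted p = 0.000175 and 0.00089), and neither with an estimated correlation (adjusted p = 0.0671 and 0.687). Of the called members, 4 of 7 flavonoid genes and 7 of 17 glutathione transferases, 6 of these higher, moved the same way in all 4 genotypes. At 10 d gst2, gst5 and gst23 were at 107, 93 and 79.8 CPM in B37 and at 19.6, 5.78 and 6.53 CPM in B37Htn1. Not called by camera were 17 WRKY genes (9 higher, 2 lower, adjusted p = 0.0864), 40 jasmonate and lipoxygenase genes (18 higher, 5 lower, 0.0726), 22 heat shock genes (10 higher, 3 lower, 0.127) and 4 wax genes (2 lower, 0.427). Their counts were the same adjusted over the list alone, and all 4 had an adjusted p of 0.687 with an estimated correlation. Phenylpropanoid genes went both ways, with 3 higher and 2 lower of 7 (3 and 3 adjusted over the list alone), a median of −0.31 and a mean of 0.31 (camera adjusted p = 0.921, and 0.926 with an estimated correlation).

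Comparing each Htn1 line with its parent asks how the lines differed before and during infection. It does not part the effect of Htn1 from that of other donor genome in a line. B37Htn1 may carry such genome on all chromosomes, as taken up below. Before inoculation, most heat shock, ribosomal protein and chitinase genes were already higher in leaves of w22Htn1 than in leaves of w22, with median log2 fold changes of 1.30, 0.89 and 3.41 over the lists. The genes an2, of phytoalexin synthesis, and opr1, of the oxo-phytodienoate reductase family, were higher, while jasmonate genes as a list went both ways. The bundle sheath genes and most mesophyll genes of the C4 lists were lower. Of the genes called at 0 h, 76.8% had the same direction at 3 d and 12.2% were called the same way. Counts of the benzoxazinoid gene bx1 and the protease gene see2a stayed low in w22Htn1 at all 4 times.

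At 0 h the ribosomal protein gene rpl10 (GRMZM2G087233) was at 364 ± 75.6 CPM in w22Htn1 and 79.9 ± 6.98 CPM in w22, a log2 fold change of 2.19 ± 0.14 (edgeR, Benjamini-Hochberg adjusted p = 5.33e-15). The glutathione transferase gene gst30 was at 88.2 ± 27.2 against 1.77 ± 1.35 CPM, and the phenylalanine ammonia-lyase gene pal3 at 27.5 ± 17.2 against 1.15 ± 0.38 CPM (edgeR, Benjamini-Hochberg adjusted p = 3.49e-07 and 4.76e-05). The heat shock gene hsp70 (GRMZM2G310431) was at 57.9 ± 38.8 against 5.57 ± 2.56 CPM, a log2 fold change of 3.37 (edgeR, Benjamini-Hochberg adjusted p = 4.84e-07), and 2.68 without w22Htn1 0 h replicate 4. The diterpene synthase gene an2 was at 133 ± 58.2 against 0.877 ± 0.576 CPM (edgeR, Benjamini-Hochberg adjusted p = 5.4e-06). The malic enzyme gene me3 was at 7815 ± 1635 against 14340 ± 870 CPM, and the rubisco small subunit gene ssu1 at 267 against 846 CPM (edgeR, Benjamini-Hochberg adjusted p = 3.23e-05 and 0.000701). In each case all 3 libraries of one line lay beyond the other line's.

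At 0 h 12226 genes were called between w22Htn1 and w22, 5796 higher and 6430 lower, and 10768 without w22 0 h replicate 4, which held 360 genes at 3 counts or fewer in all other w22 libraries (19 and 30 such genes in replicates 1 and 3, at most 184 in a w22 library of a later time, and 310 by the same count in B37 10 d replicate 4). Ribosomal genes were called higher in 20 of 27 cases and lower in 1 (20 and 3 adjusted over the list alone), and heat shock genes higher in 16 of 22 and lower in 1 (17 and 1 adjusted over the list alone). Chitinase and beta-glucanase genes were higher in 4 of 5 cases and genes of dividing cells in 4 of 10; 4 of 4 bundle sheath and 6 of 7 mesophyll genes were lower, the same counts adjusted over the list alone. Camera called these 6 lists (adjusted p = 6.3e-07, 0.000304, 0.0375, 0.0375, 0.0432 and 0.0315), and none of them with an estimated correlation (adjusted p = 0.151 for heat shock and 0.459 for the others). The chitinase list member not called, chi1, is a chalcone isomerase and was kept in the list here. Of the mesophyll members of another role, pdlk1 and pdk1 (GRMZM2G097821) were among the lower genes. Without these and pep1 (GRMZM5G899080), 4 of 4 were lower and the list was not called (camera adjusted p = 0.0660, and 0.431 with an estimated correlation). Photosystem genes were lower in 7 of 10 cases and higher in 1, psat1, by both counts, and were not called (camera adjusted p = 0.137, and 0.729 with an estimated correlation). Jasmonate and lipoxygenase genes were higher in 17 of 40 cases and lower in 13 (17 and 14 adjusted over the list alone), and were not called (camera adjusted p = 0.441, and 0.798 with an estimated correlation).

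The gene bx1, for the first step of benzoxazinoid synthesis, was at 1.65 ± 0.504 CPM in w22Htn1 and 96.1 ± 45.5 CPM in w22 at 0 h, and at 19.7 ± 23.8 and 236 ± 109 CPM at 10 d. The log2 fold changes at 0 h, 9 h, 3 d and 10 d were −5.89 ± 0.93, −4.81 ± 0.83, −4.10 ± 0.79 and −3.57 ± 0.76 (edgeR, Benjamini-Hochberg adjusted p = 2.83e-06, 5.16e-05, 0.000348 and 0.00107). The last was −5.29 without w22Htn1 10 d replicate 2. At 9 h, 5 of 11 benzoxazinoid genes were lower and 2 higher (7 and 2 adjusted over the list alone), and camera called the list (adjusted p = 0.0368), but not with an estimated correlation (adjusted p = 0.507). This list is not independent evidence, since work on Htn1 had already written on the pathway from such samples. The protease gene see2a was at 10.8 ± 2.59 against 129 ± 20.9 CPM at 0 h and 18.7 ± 1.89 against 121 ± 8.78 CPM at 10 d; at 3 d its log2 fold change was −2.49 ± 0.14 (edgeR, Benjamini-Hochberg adjusted p = 1.1e-16).

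At 9 h 4928 genes were called in w22Htn1, and 3077 without w22 9 h replicate 1. The lists called at that time besides the benzoxazinoid genes were ribosomal (13 higher, 1 lower; 18 and 2 adjusted over the list alone; camera adjusted p = 5.55e-05), mesophyll (4 lower; 5; 0.00119), bundle sheath (3; 4; 0.0101) and photosystem genes (4; 5; 0.0325), heat shock genes (6 higher by both counts; 0.0368) and proteinase inhibitors (3 of 10 higher by both counts; 0.0368). With an estimated correlation their adjusted p ran from 0.377 to 0.536. At 3 d 1937 genes were called and at 10 d 2353, or 1547 without w22 10 d replicate 1 and 555 in a fit of the compared groups alone. Camera called 0 lists at 3 d and at 10 d.

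**Figure D2:**
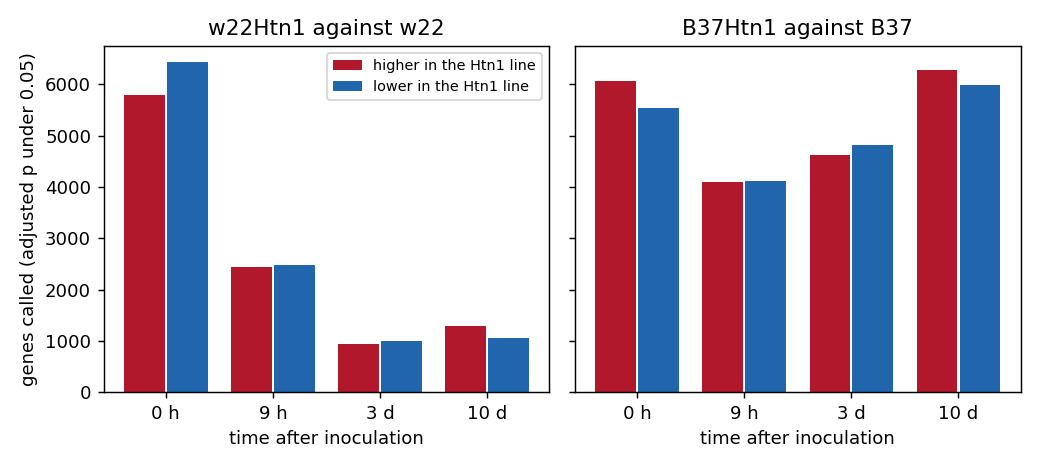
Number of genes called higher and lower (bars, counts) in each Htn1 line than in its parent at each time. In w22Htn1 the number fell from 12226 at 0 h to 1937 at 3 d, while in B37Htn1 it was 11615 at 0 h and 12268 at 10 d.

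In the B37 background, the line and its parent differed at every time, in 11615 genes at 0 h and in 12268 at 10 d. At 10 d, the chitinase genes, most flavonoid genes and a part of the heat shock and jasmonate genes were lower in B37Htn1 than in B37. The 4 mesophyll genes of the C4 cycle, without members of another role, were higher in B37Htn1. At 9 h, the bundle sheath genes and most photosystem genes had been lower in B37Htn1.

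At 10 d the chitinase gene chn1 was at 1291 ± 331 CPM in B37 and 45.9 ± 39.1 CPM in B37Htn1, the pathogenesis-related gene prp4 at 868 ± 308 and 22 ± 29.5 CPM, and fht1 at 52.5 ± 20.5 and 0.525 ± 0.764 CPM. Their log2 fold changes were −4.82, −5.34 and −6.86 (edgeR, Benjamini-Hochberg adjusted p = 2.24e-06, 8.36e-05 and 3.12e-08), and −5.75, −7.37 and −8.91 without B37Htn1 10 d replicate 2; fht1 gave −6.27 without B37Htn1 10 d replicate 4. The heat shock gene hsp70 (GRMZM2G310431) was at 213 ± 33.8 and 13.5 ± 4.42 CPM, a log2 fold change of −3.97 ± 0.46 (edgeR, Benjamini-Hochberg adjusted p = 9.14e-09). The lipoxygenase gene lox7 had a log2 fold change of −4.25 ± 0.58 and the allene oxide synthase gene aos1 one of −2.88 ± 0.69, both of jasmonate synthesis (edgeR, Benjamini-Hochberg adjusted p = 1.78e-07 and 0.000735). Of the C4 genes, me3 was at 15717 ± 805 CPM in B37Htn1 and 6322 ± 473 CPM in B37, and ppdk2 was higher by 3.45 ± 0.35 (edgeR, Benjamini-Hochberg adjusted p = 2.95e-08 and 4.74e-10). In each case all 3 libraries of one line lay beyond the other line's.

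**Figure D3:**
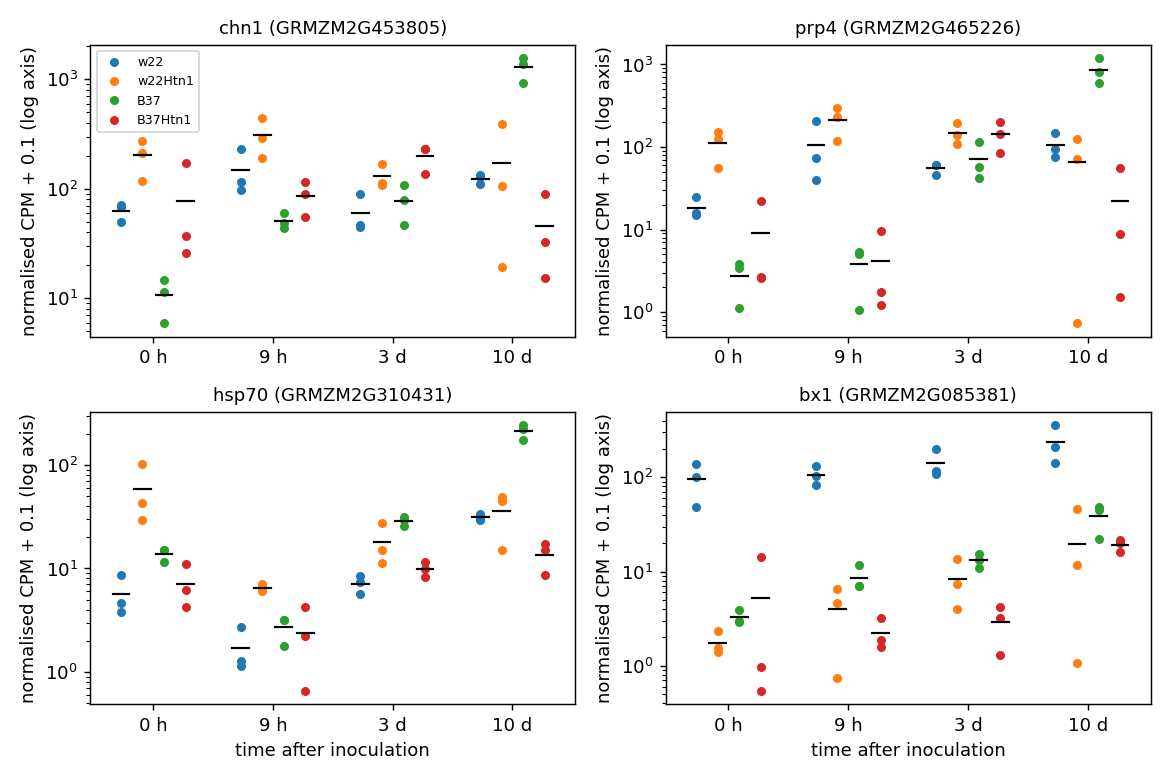
CPM plus 0.1 (log axis) of chn1, prp4, hsp70 and bx1 in each of the 48 libraries by genotype and time; points are libraries and bars are means of 3. At 10 d chn1, prp4 and hsp70 are highest in B37, and bx1 is highest in w22 at every time.

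At 10 d 12268 genes were called, 6286 higher and 5982 lower in B37Htn1. Flavonoid genes were lower in 7 of 8 cases, chitinase and beta-glucanase genes in 5 of 5, dividing-cell genes in 5 of 10, and mesophyll genes were higher in 5 of 7. Glutathione transferases were lower in 19 of 29 cases and higher in 2, jasmonate and lipoxygenase genes lower in 20 of 40 and higher in 3, heat shock genes lower in 12 of 22 and higher in 1, and proteinase inhibitors lower in 7 of 10 and higher in 1. All these counts were the same adjusted over the list alone. Camera called the 8 lists, at adjusted p = 0.00244, 0.00628, 0.012, 0.0226, 0.00593, 0.00671, 0.0179 and 0.0494 in that order, and none with an estimated correlation (adjusted p from 0.201 to 0.401). Pathogenesis-related genes were lower in 4 of 5 cases by both counts and were not called (camera adjusted p = 0.12, and 0.401 with an estimated correlation); without win1, a transcription factor, the list was called (0.0352), but not with an estimated correlation (0.406). Among these members, chi1 is a chalcone isomerase and pdlk1 a kinase; without members of another role 4 of 4 chitinase genes were lower (camera adjusted p = 0.00692) and 4 of 4 mesophyll genes higher (0.0465), neither list called with an estimated correlation (0.353 and 0.406). Wax genes were higher in 4 of 4 cases by both counts (camera adjusted p = 0.164, and 0.401 with an estimated correlation), one of them the regulator gl15.

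At 9 h 8214 genes were called between B37Htn1 and B37; all 4 bundle sheath genes and 7 of 10 photosystem genes were lower (4 and 8 adjusted over the list alone). Camera called both lists at adjusted p = 0.0308, and neither with an estimated correlation (adjusted p = 0.943 for both). Mesophyll genes were lower in 4 of 7 cases and higher in 1, pdlk1, by both counts, and were not called (camera adjusted p = 0.664, and 0.943 with an estimated correlation); without members of another role 3 of 4 were lower (0.0977, and 0.898 with an estimated correlation). The malic enzyme gene me3 was at 1923 ± 243 CPM in B37Htn1 and 8002 ± 525 CPM in B37 (edgeR, Benjamini-Hochberg adjusted p = 1.46e-12), with all 3 libraries beyond the other line's. At 0 h 11615 genes were called; ribosomal genes were higher in 20 of 27 cases and lower in 4 by both counts (camera adjusted p = 0.00376, and 0.93 with an estimated correlation). At 3 d 9448 genes were called and 0 lists. The genes gst1 (2.62 against 242 CPM at 0 h) and pdlk1 (3.33 against 48.1 CPM) were far higher in B37Htn1 at all 4 times, with log2 fold changes of 4.89 to 6.54 and 3.77 to 4.01 and an edgeR Benjamini-Hochberg adjusted p of at most 4.29e-18.

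Genes called the same way in both backgrounds may reflect something the lines have in common, but independent lists would share many genes as well. The genes called this way included an aquaporin, a starch-synthesis gene and a bHLH factor, all higher in both Htn1 lines at all 4 times. The genes mir169d and amadh1, an aminoaldehyde dehydrogenase gene, were lower. All of these genes lie on chromosome 4, from 35609001 (bhlh172) to 153658268 (pip1-3), and not on chromosome 8 with Htn1. The windows of 5 Mb that hold mir169d and pip1-3 were called in both lines, so linked donor genome may account for them. At 0 h the same direction was called in both for 4654 genes where independent lists would give 3033, and opposite directions for 1816 genes where 3048 would be drawn. At 9 h 1387 genes were shared against 867, at 3 d 608 against 392 and at 10 d 720 against 620, with 649 opposite against 867, 372 against 392 and 575 against 616. Without genes in windows of 5 Mb called in either line, 3500 were shared against 2211 at 0 h, 862 against 547 at 9 h, 275 against 186 at 3 d and 347 against 340 at 10 d. The opposite counts there were 1275 against 2225, 416 against 546, 200 against 186 and 328 against 332. The count at 10 d was 1148 without w22Htn1 10 d replicate 4 and 151 in a fit of the compared groups alone.

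The aquaporin gene pip1-3 had mean log2 fold changes of 1.46 in w22Htn1 and 1.39 in B37Htn1, with 70 against 22.7 CPM and 203 against 75.8 CPM (means of 12 libraries). The gene bt2, for a subunit of ADP-glucose pyrophosphorylase, had 1.09 and 1.93, and bhlh172 0.53 and 0.65. The dehydrogenase gene amadh1 was lower, with −1.11 and −1.75, with 17.6 against 38 CPM and 14.7 against 47.7 CPM. Called lower at all 4 times in both backgrounds were also sbe3, a starch branching enzyme gene, smh1, of a histone-like family, and mir169d, which went from 6.56 to 0.33 CPM in w22Htn1 and from 3.08 to 0.00921 CPM in B37Htn1. Some of these calls depended on 1 library. In w22Htn1 at 9 h, pip1-3 lost its call without w22 9 h replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0803). At 10 d, sbe3 lost its call in w22Htn1 without w22 10 d replicate 1 or w22Htn1 10 d replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.05, by a margin under rounding, and 0.0902), and in B37Htn1 without B37Htn1 10 d replicate 2 (0.0535). In w22Htn1, smh1 lost its call at 0 h without w22 0 h replicate 1 and at 10 d without w22Htn1 10 d replicate 4 (edgeR, Benjamini-Hochberg adjusted p = 0.0509 and 0.0597), and at 0 h also in a fit of the compared groups alone (0.0846).

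The positions of these genes were compared along the chromosomes of B73 RefGen_v3. In w22Htn1, genes that differed at all 4 times clustered on chromosomes 1, 4, 5 and 8, including a continuous stretch of chromosome 8. In B37Htn1 they lay on all 10 chromosomes. The windows that hold bx1, bx6 and see2a are among those called in w22Htn1. Whether genes there differ in expression or only in how their reads align to B73 was not tested.

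In w22Htn1 795 genes were called the same way at all 4 times, 354 higher and 441 lower (371 in a fit of the compared groups alone), and 41 of 416 windows of 5 Mb held more of them than other genes did (Fisher's exact test, one-sided, adjusted p = 8.03e-20 for the lowest). These windows, 16 in a fit of the compared groups alone, lay on chromosomes 1 (10 windows), 4 (17), 5 (6) and 8 (8) and held 60% of the genes. On chromosome 8 they ran without a gap from 130000001 to 170000000, and see2a lies there at 137286214 to 137293588. The first window of chromosome 4, up to 5000000, held 21 such genes of 98 (Fisher's exact test, adjusted p = 1.06e-09), with bx1 at 3260762 to 3263006 and bx6 at 1252638 to 1254044. In B37Htn1 2860 genes were called at all 4 times, 1448 higher and 1412 lower. The 41 windows called there lay on 10 chromosomes and held 28.5% of the genes, but with windows of 2 Mb only 7 were called (50 in w22Htn1). The share of tested genes ran from 6.72% on chromosome 5 to 19.2% on chromosome 6. Only 5 windows were called in both lines, on chromosomes 1, 4 and 8.

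**Figure D4:**
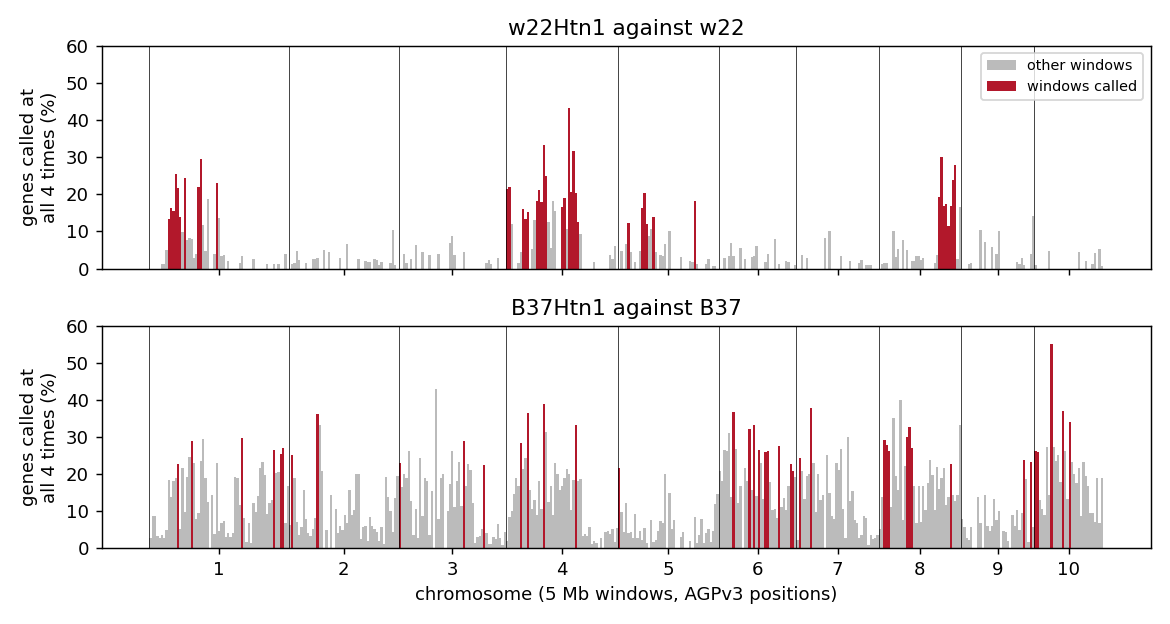
Share of tested genes (percent) called the same way at all 4 times in windows of 5 Mb along the 10 chromosomes, for w22Htn1 and B37Htn1; marked windows passed the test. In w22Htn1 they lie on chromosomes 1, 4, 5 and 8, and in B37Htn1 on all 10, where windows of 2 Mb gave only 7.

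The only gene that the reference names as a wall-associated kinase, wak-rlk2 (GRMZM2G144028), lies at 151442240 to 151450110 on chromosome 8, inside the stretch called in w22Htn1. Whether it is the cloned gene is not given in the sources used here. Its transcript was low, at 3.15 to 18.2 CPM in the 16 groups. It was not called between w22Htn1 and w22 at any time (log2 fold changes from −0.96 to 0.61), and in B37Htn1 it was called only at 10 d, at 5.66 ± 3.36 against 18.2 ± 5.26 CPM in B37 (log2 fold change −1.70 ± 0.46, edgeR, Benjamini-Hochberg adjusted p = 0.0021, all 3 libraries below). Over time it rose by 1.09 ± 0.24 at 10 d, in 3 of 4 genotypes (edgeR, Benjamini-Hochberg adjusted p = 0.000211).

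The response difference asks whether a line and its parent changed differently after inoculation. In w22 the named genes with the lowest response differences at 10 d included some that were high in w22Htn1 before inoculation and came down to near the parent's level. At 10 d opr1 and opr2, of the oxo-phytodienoate reductase family, went from 68.3 and 87.2 CPM at 0 h to 2.29 and 2.51 CPM in w22Htn1, and from 0.279 and 0.38 to 3.77 and 3.49 CPM in w22 (edgeR, Benjamini-Hochberg adjusted p = 3.41e-05 and 9.5e-05). In the same way an2 went from 133 to 9.84 CPM against 0.877 to 10.8 CPM, and the alternative oxidase gene aox3 from 37.1 to 5.75 CPM against 0.64 to 4.9 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.000369 and 0.000855). With 1 library left out at a time these 4 kept their calls; the response difference of opr1 moved most from −8.41 to −9.55 (without w22 0 h replicate 3), of opr2 from −8.09 to −9.77 (w22Htn1 10 d replicate 1), and of an2 and aox3 from −7.44 to −8.25 and from −5.67 to −7.10 (w22Htn1 10 d replicate 4). The annexin gene ann5 went the other way, from 0.812 to 12.3 CPM in w22Htn1 and from 11.2 to 19.9 CPM in w22 (edgeR, Benjamini-Hochberg adjusted p = 0.00315, and 0.019 without w22Htn1 10 d replicate 4).

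In w22, the test of the response difference called 4257 genes at 9 h, 5320 at 3 d and 7273 at 10 d. Without w22Htn1 0 h replicate 1 the first 2 counts were 2587 and 3009, and in fits of the compared groups alone 2406 genes were called at 9 h and 2494 at 10 d. At 10 d ribosomal genes were lower in 20 of 27 cases and higher in 2 (21 and 2 adjusted over the list alone), and heat shock genes lower in 13 of 22 (14 adjusted over the list alone). Camera called both lists (adjusted p = 6.48e-09 and 1.07e-05). With an estimated correlation the adjusted p was 0.362 and 0.0431, so only the heat shock list kept its call, the only list in any comparison to do so. At 0 h 21 ribosomal and 17 heat shock genes were called between w22Htn1 and w22, most of them higher in w22Htn1. At 10 d 4 and 0 were called. The response differences of these lists thus include the line difference at 0 h. The ribosomal gene rps24 had a response difference of −1.84 ± 0.30, and hsp70 (GRMZM2G310431) of −3.18 ± 0.63 (edgeR, Benjamini-Hochberg adjusted p = 3.44e-05 and 0.000297); the latter was −2.48 without w22Htn1 0 h replicate 4.

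In B37 the named genes with the lowest response differences at 10 d included some that rose in B37 and not in B37Htn1. The wound-induced gene wip1 went from 1.63 to 120 CPM in B37 and from 22 to 1.81 CPM in B37Htn1 (edgeR, Benjamini-Hochberg adjusted p = 9.29e-06). Its response difference was −9.62, and −4.85 without B37Htn1 0 h replicate 3, −10.33 without B37 0 h replicate 4 and −10.54 without B37Htn1 10 d replicate 3. The benzoxazinoid gene bx14 went from 0.0312 to 127 CPM in B37 and from 2 to 0.577 CPM in B37Htn1 (edgeR, Benjamini-Hochberg adjusted p = 1.17e-05), but its call was lost without B37Htn1 0 h replicate 3 (adjusted p = 1). The gene zcn18 went from 0.802 to 23.9 CPM in B37Htn1 and from 14.1 to 15.6 CPM in B37, a response difference of 4.76 ± 0.62 (edgeR, Benjamini-Hochberg adjusted p = 4.28e-07). The heat shock gene hsp70 (GRMZM2G310431) gave −2.99 ± 0.63 (edgeR, Benjamini-Hochberg adjusted p = 0.000251).

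In B37, the test of the response difference called 4149 genes at 9 h, 1141 at 3 d and 10037 at 10 d. In fits of the compared groups alone the first 2 counts were 6514 and 1768. The count at 3 d was 655 without B37 0 h replicate 1, 646 without B37 0 h replicate 4, 617 without B37Htn1 0 h replicate 4, 602 without B37 3 d replicate 4 and 625 without B37Htn1 3 d replicate 1. At 10 d ribosomal genes were lower in 21 of 27 cases and higher in 2 (23 and 3 adjusted over the list alone), and flavonoid and chitinase genes lower in 3 of 8 and 3 of 5 by both counts. Camera called these lists (adjusted p = 7.38e-06, 0.000821 and 0.0009) and none with an estimated correlation (adjusted p = 0.285, 0.169 and 0.285). Between B37Htn1 and B37, 20 ribosomal genes were higher and 4 lower at 0 h, and 4 were higher and 7 lower at 10 d. The response difference of the ribosomal list thus includes the line difference at 0 h. The mean effect of the line differed between the backgrounds in 12264 genes, 6115 higher in B37 and 6149 lower.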

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

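The tests of response differences and of the difference between backgrounds were planned, as were the splits for the latter, the fits without 1 library and the tests of swapped libraries and of depth; the other tests in this part, and the use of a fit without 1 library as a test of an explanation, were chosen after results were seen.

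The test of whether a line and its parent changed differently from 0 h called 4257 genes at 9 h, 5320 at 3 d and 7273 at 10 d in w22, and 4149, 1141 and 10037 in B37. Since each is measured from 0 h, where the lines already differed, these counts alone do not show a different change after inoculation. The mean effect of the line differed between the backgrounds in 12264 genes.

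Other splits of the same libraries were fitted to ask whether such counts arise by chance. For the changes over time, 1 of 100 splits gave as many genes, the real one, with 15334, 11119 and 11310 genes at 9 h, 3 d and 10 d against at most 9120, 2972 and 5693 in the other splits, so chance can be excluded. For the difference between backgrounds, 1 of 100 splits gave as many genes, the real one (12264 genes, highest other 2896). Of the other splits, 0 kept the lines apart at 0 h in both backgrounds. They ask whether the lines differ at all, not whether they differ equally in both backgrounds, so they cannot decide this question. Chance cannot be excluded for the response differences in w22 at 9 h (2406 genes, 6 of 100, highest other 7351), 3 d (4118, 8 of 100, 7274) and 10 d (2494, 9 of 100, 6202), nor in B37 at 3 d (1768, 5 of 100, 6907). The splits that called as many genes or more, up to several times the real count, all kept the 2 lines apart before inoculation. They point to a structure of the samples, the line difference at 0 h. In B37 2 of 100 splits were as large at 9 h (6514 genes, highest other 7037) and 1 of 100 at 10 d (10058, highest other 4691). All of these kept the lines apart at 0 h, as only 7 and 8 of the other splits drawn did. So few are too few for a share under 0.05 among them, and the low shares do not show a response beyond the difference at 0 h.

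For each line against its parent, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 8929, 3880, 1785 and 555 genes in w22 at 0 h, 9 h, 3 d and 10 d, and the highest other split 0, 0, 1 and 0. In B37 it gave 11642, 9662, 9081 and 10486 genes, and the highest other split 0 at each time.

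The first pattern is that B37Htn1 differed from B37 on every chromosome, while w22Htn1 differed mainly on chromosomes 1, 4, 5 and 8. For genes called at all 4 times, the order of directions was used to ask about leaf states that varied between times. Of 3347 such genes, 2860 had the same direction at each time, and the highest of the 7 other orders held 410. That order was opposite only at 10 d. States whose effect turned round between times therefore do not account for most of these genes. A leaf state that kept its direction at all times would give the same order as a lasting line difference, so the test cannot decide on it. Genes that differed at a single time were left out by this choice, so the test does not bear on them. Swaps of single libraries are argued against, since 0 of 24 libraries matched the other line at more than 50% of marker genes. Each matched its own line at 97.3% or more. Among the w22 and w22Htn1 libraries the lowest was 78.9%, in w22 0 h replicate 4. The markers were set from the line labels at the other 3 times. A line misnamed at every time would therefore match itself, and the test cannot detect it. Donor genome left on all chromosomes is consistent with 305 genes at 1 CPM or more in all 12 libraries of one line and at 3 counts or fewer in all 12 of the other (165 seen only in B37Htn1 and 140 only in B37), which compare with 331 between w22 and B37 and 50 between w22 and w22Htn1 (429 and 65 without that w22 library). B37Htn1 may thus carry donor genome far beyond Htn1, which would let any of it contribute to the difference from B37.

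The second pattern is that leaves of w22Htn1 stood apart from w22 before inoculation, with heat shock and ribosomal genes high. A lasting difference as large as before inoculation is argued against by the fall in genes called, from 12226 at 0 h to 1937 at 3 d. The median log2 difference of the genes called at 0 h went from 1 to 0.195 at 3 d. Since these genes were chosen at 0 h, part of that fall comes from the choice, and its size was not measured. A smaller lasting difference stays open, since 76.8% had the same direction at 3 d. Unusual leaves of the parent are argued against by the ratio of genes that changed between 0 h and 3 d, 3.96 times as many in w22Htn1 (11291) as in w22 (2850), and 5.31 times without w22 0 h replicate 4. Passing stress in the sampled w22Htn1 leaves is consistent with a Spearman correlation across genes of 0.423 between the difference at 0 h and the change of B37 leaves from 0 h to 10 d, against 0.198, 0.248 and −0.0911 for the line difference at 9 h, 3 d and 10 d; genes are not independent replicates. No stress was measured, and a cause shared by both Htn1 lines stays open, since 20 of 27 ribosomal genes were also higher in B37Htn1 at 0 h and 4654 genes had the same direction in both lines, where 3033 would be drawn; heat shock genes went both ways in B37Htn1, with 4 higher and 5 lower of 22 (16 and 1 in w22Htn1).

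The third pattern is that B37 leaves at 10 d stood apart from B37Htn1 leaves, with chitinase genes high and mesophyll C4 genes low. The lower depth of the B37 libraries is argued against, since thinning the 12 libraries to 8.55 M counts gave 9037 response differences, against 10058 without thinning in the fit of the compared groups alone. The B37Htn1 library before inoculation that stood apart, replicate 3, is argued against as the whole cause, since 8698 were called without it, against 10037 with it in the fit of all 16 groups. Less disease in B37Htn1 would lower pathogenesis-related and chitinase genes, and without members of another role 8 of 8 were lower at 10 d; in w22Htn1 edgeR called 0 of the 8 (0 at an unadjusted p under 0.05, 6 higher and 2 lower), where the replicates held 0.631, 70.7 and 126 CPM of prp4, and the line difference itself was lower in B37 than in w22 for 8 of 8. Disease and other differences between the lines cannot be told apart here, since no uninoculated leaves were sampled at 10 d.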

How the results depend on the processing

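Most tests in this part were planned; the mean over time without w22Htn1 and the list tests without members of another role were chosen after results had been seen.

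RLE scaling, no filter on low counts and DESeq2 left all 26 counts of genes or windows within 1.5 times the value reported. Of 90 calls of single named genes, RLE and DESeq2 kept all 90 and the fit with no filter 86; icl1 at 9 h, lol3 and mas1 in the response in w22 and m2 in that in B37 lost theirs. The medians over all genes lay between −0.064 and 0.079 on the log2 scale under TMM, RLE and DESeq2. Of 1687 calls of list members, 1660, 1580 and 1655 were kept under RLE, no filter and DESeq2, and 0 turned. Without the line w22Htn1, 15554, 10679 and 13508 genes were called at 9 h, 3 d and 10 d.

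The replicate numbers do not pair the samples: deviations from the group means correlated at −0.00693 on average between libraries of the same number and at 0.00279 between others, and 7 of 48 libraries correlated best with their own number. With the replicate number as a block, 15262 genes were called at 9 h, 11082 at 3 d and 12050 at 10 d, 4086, 5181 and 6616 for the response differences in w22, 3676, 1071 and 9548 in B37, and 12069 between backgrounds. All 26 counts stayed within 1.5 times, and 87 of the 90 named calls were kept. The calls of lol3 in the response in w22 and of hsbp1 and icl1 in that in B37 were lost. Of 1687 calls of list members, 1607 were kept and 0 turned.

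Fits of the compared groups alone share no spread with other groups, and 17 of 25 counts stayed within 1.5 times. The others were 555 genes for w22Htn1 at 10 d, 2406 and 2494 for the response in w22 at 9 h and 10 d, 6514 and 1768 for the response in B37 at 9 h and 3 d, 371 genes at all 4 times and 16 windows in w22Htn1, and 151 genes shared by both backgrounds at 10 d. Of 89 named calls 79 were kept. Those lost over time and between lines were tps3 (GRMZM2G064406) at 3 d and 10 d and smh1 in w22Htn1 at 0 h. In the responses, expa5, lol3, mas1 and pmp3 in w22 and m2, lox1 and tps10 in B37 lost theirs. Of 1480 calls of list members, 1295 were kept and 0 turned. The cause was not tested.

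Windows of 10 Mb gave 26 calls in w22Htn1 and windows of 2 Mb 7 in B37Htn1. Over all comparisons, camera called 54 lists with the preset correlation, 1 with an estimated correlation and 60 without members of another role, and fry, which compares a list with no other genes, called 150.

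Leaving out 1 library at a time gave 2587 to 5245 genes for the response in w22 at 9 h and 3009 to 6537 at 3 d, both lowest without w22Htn1 0 h replicate 1. For the response in B37 at 3 d it gave 602 to 1285, lowest without B37 3 d replicate 4. For w22Htn1 it gave 3077 to 4917 at 9 h, lowest without w22 9 h replicate 1, and 1547 to 3277 at 10 d, lowest without w22 10 d replicate 1. Genes shared by both backgrounds at 10 d ran from 527 without w22 10 d replicate 1 to 1148 without w22Htn1 10 d replicate 4. All other counts stayed within 1.5 times. Of the calls behind named genes, 4 of 30 over time, 20 of 143 between lines and 8 of 20 response differences were lost in some such fit. Of 1555 calls of list members 1118 were kept in every fit, and 11 turned in some fit. The cause was not tested.

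Depth limits genes near the floor of 0.125 to 0.462 CPM, such as r1 and hao1 at 0 h. In the simulated comparison at 3 d, 61 of 100 genes changed by 2-fold were recovered, so the counts of calls miss part of the differences of that size.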

Other observations

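The tests of a shared donor segment and of RNA from another genotype were chosen after results were seen.

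Some differences between a line and its parent were marked at particular times, and that of hsp90-1 turned round between 9 h and 10 d. At 9 h B37Htn1 leaves held 338 ± 103 CPM of the chaperone gene hsp90-1 and B37 leaves 61 ± 19.1 CPM, the reverse of 10 d, when it was at 126 ± 46.4 and 587 ± 73.4 CPM (edgeR, Benjamini-Hochberg adjusted p = 1.66e-07 and 7.22e-07 for the 2 times). The allene oxide cyclase gene aoc1, of jasmonate synthesis, was at 0.823 ± 0.614 CPM in w22Htn1 and 2.83 ± 0.395 CPM in w22 at 0 h, and at 0.234 ± 0.0385 and 5.12 ± 1.48 CPM at 10 d (edgeR, Benjamini-Hochberg adjusted p = 0.00623 and 1.95e-06). In B37Htn1 the chlorophyll breakdown gene sgr2 was at 13.1 ± 4.14 CPM at 3 d and at 2.26 ± 1.14 CPM in B37 (edgeR, Benjamini-Hochberg adjusted p = 2.5e-05), and the flowering-family gene zcn18 was at 0.802 ± 0.397 CPM at 0 h against 14.1 ± 4.38 CPM (edgeR, Benjamini-Hochberg adjusted p = 1.05e-08). For each of these differences, all 3 libraries of one line lay beyond the other's. At 10 d aoc1 lay near the floor in w22Htn1.

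Some libraries stood apart from their replicates. B37Htn1 0 h replicate 3 held 439 CPM of the terpene synthase gene tps10, where the other replicates held 0.189 and 0.731 CPM, and 301 CPM of the lipoxygenase gene lox1, where they held 0.441 and 0.366 CPM. The chitinase gene chn1 was at 171 CPM against 36.9 and 25.7 CPM. At 10 d, w22Htn1 replicate 2 held 8.46 CPM of pr5 and 0.631 CPM of prp4, and replicates 1 and 4 held 144 and 494 CPM of pr5 and 70.7 and 126 CPM of prp4.

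Before inoculation, w22 replicate 4 matched its own line at 78.9% of 71 marker genes, where the other 47 libraries matched at 91.8% or more, and it lay at 67.2 on the first principal component, where replicates 1 and 3 lay at 103.4 and 97. Of 253 genes that were at 3 counts or fewer in w22 at all later times and at 1 CPM or more in all 12 B37 libraries, it held 98, or 38.7%. By the same kind of test the highest share in the other 47 libraries was 5.18%. RNA of another maize genotype in that library is consistent with this; which genotype stays open. Without it, 10768 genes were called between w22Htn1 and w22 at 0 h, and 3458, 4116 and 6467 for the response in w22 at 9 h, 3 d and 10 d. The genes called at all 4 times were 787 and the windows 36.

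Genes called at all 4 times in both backgrounds had the same direction in 164 cases (74 higher, 90 lower), where independent lists would give 48.6, and the opposite direction in 60. If both lines carry the same donor segment around Htn1, genes there would differ in the same direction in both. On chromosome 8, 47 of 58 such genes, or 81%, had the same direction, but so did 60 of 70, or 85.7%, on chromosome 4, where Htn1 does not lie (sign tests, Benjamini-Hochberg adjusted p = 1.02e-05 and 8e-09). Chromosome 1 held 22 of 42, and the other 7 held 3 to 14 such genes each, too few to tell by themselves (6 of 7 on chromosome 6, and 3 of 3 on chromosomes 7 and 10). A shared segment around Htn1 and another source of shared direction cannot be told apart by these shares, since chromosome 4 matched chromosome 8, and no sequence variants were analysed here.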
